A study of Mus musculus with 3 samples.

How the data were processed

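The material was bone marrow B cells of mice that carry PAX5-ELN, a fusion of the B cell transcription factor PAX5 with elastin that gives rise to B cell leukemia. Per the labels, cells were flushed from femurs and tibias, sorted with antibodies that mark B cells, stained with oligonucleotide-tagged hashtag antibodies (TotalSeq-C) and pooled. The 3 libraries of the pool, made with version 2 of the 10x Genomics 5 prime kit, held gene expression, B cell receptor and hashtag sequences. A single pre-leukemic PAX5-ELN mouse, leukemic PAX5-ELN mice and leukemic PAX5-ELN mice without Lgals1, the gene of galectin-1, were pooled, with 7 hashtags for 7 mice. Ages of 6, 10, 16, 26, 27, 47 and 53 weeks stood in the labels without a map to the mice, so age was not used.

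The deposited matrix held UMI counts per gene and hashtag for 10805 barcodes, 32286 genes and 7 hashtags, with PAX5-ELN as a feature of its own. The authors made these counts with Cell Ranger. The version differed between sources: 7.1.0 per the file headers and 8.0.1, with genome build mm10, per the submitters' processing notes. The deposited contig table held UMI counts and read counts per assembled receptor contig, and the contigs in it were productive and of high confidence. The counts were not normalized by the authors. Positions of genes came from a RefSeq gene table of assembly GRCm38.p6, which has the coordinates of mm10. Of the tested genes, 12874 (95.2%) were matched to it by symbol.

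Both deposited sources that name the hashtags gave the pre-leukemic mouse hashtag 7, but they gave another genotype to 5 of the 7 hashtags. A separate hashtag table named hashtags 1 to 3 as Lgals1-/- and 4 to 6 as the leukemic mice without that deletion, written Lgals1+/+ here. The feature table beside the matrix named hashtags 1 and 2 as Lgals1+/+ and 3 to 6 as Lgals1-/-. The design fixed before the data were examined named the hashtag table. When the conflict was first seen, the feature table was taken in its place, before any expression value per hashtag had been seen. The hashtag table was taken again after the Lgals1 level of each hashtag was known. The Lgals1 level is therefore no independent check of these names. The edgeR tests, the gene list tests and the comparisons of values per mouse between genotypes were also computed with the names of the feature table. No such values are given for DESeq2 or for the genes around Lgals1.

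Barcodes with at least 500 genes, at least 1000 UMIs and under 10% mitochondrial UMIs were kept, which left 10479 barcodes and removed 326. Hashtags were called over all 10805 barcodes with HTODemux of Seurat 5.3.0 (centred log ratio over cells, positive quantile 0.99, seed 42). It called 8503 singlets, 2178 doublets (20.2%) and 124 negatives. The 8259 singlets that passed the filters were used. Doublets between mice were left out with the hashtags. Doublets within a mouse stayed in, because scrublet marked 0 cells and thus had not worked here.

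UMI counts were summed per mouse, so that the mouse and not the cell was the replicate, and every mouse had more than the 50 cells required. Genes passing filterByExpr (13524) were tested with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM scaling), with all 3 groups in a single fit and Benjamini-Hochberg adjustment at 0.05. DESeq2 1.42.0 was run beside it. Levels are given in CPM, a gene's counts scaled to the total of each mouse. The spread of the single pre-leukemic mouse was taken from the leukemic groups. On simulated counts with 200 genes changed, the genotype comparison recovered 54.7% (105 of 192 genes that were tested, among 13125 genes) at a log2 fold of 2 and 69.4% (134 of 193, among 13101) at a log2 fold of 3. The comparison with the pre-leukemic mouse recovered 7.18% (14 of 195, among 13142) and 51.5% (101 of 196, among 13124). With 200 genes changed, the adjusted threshold is easier to reach than with few changed genes. The rates therefore do not give the recovery of a lone changed gene. DESeq2 was not run on the simulated counts. Gene lists were tested with camera on voom values (limma 3.58.1, preset correlation 0.01), beside camera with an estimated correlation and fry. Of 36 lists fixed before the data were examined, 32 had at least 5 measured members and 4 were too small. In 10 simulated sets of 32 lists without any effect, camera called 2 lists in all. The simulated genes varied independently of each other. The check therefore does not cover lists with correlated members, such as the G2/M list with an estimated correlation of 0.86.

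The genes to be named were fixed by a rule. Per comparison and direction it took up to 12 genes with adjusted p under 0.05, at least 20 CPM in the mean of 1 group, no overlap between the groups' mice and no immunoglobulin segment, Gm or Rik name, ordered by log2 fold change. With fewer than 5 such genes, the 8 with the smallest unadjusted p were named as not passing. From each list, 2 to 4 members with the smallest p were to be named, which was done for the lists that passed camera. Lgals1, Igll1, Vpreb1, Il7r, Rag1, Cd19, Mki67 and Cxcr4 were always given. Genes outside this rule are said to be chosen after their values were seen.

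A clone was the set of cells of a mouse with the same heavy chain V gene, J gene and CDR3 nucleotide sequence, over cells with a productive heavy chain contig. The effective number of clones was the inverse Simpson index at 472 cells per mouse, averaged over 100 subsamples. Shares of cells carry exact Clopper-Pearson intervals at 95%, which cover counting error only. Cell cycle phases were scored with scanpy 1.11.5 after each cell was thinned to 2000 UMIs. Clusters came from 2000 variable genes without immunoglobulin, T cell receptor, mitochondrial and ribosomal genes, scaled to 10000 counts per cell, with 30 components, 15 neighbours and Leiden resolution 0.5 (leidenalg 0.10.2). A cluster was named from markers fixed before the data were examined. Settings chosen after the clusters had been seen were these: a name needed 50% of its markers raised, clusters with over 3% mitochondrial UMIs were called low quality, and a cluster with over 80% of its cells from 1 mouse counted as that mouse's own. Genes highest in a single mouse were the 5 per mouse, at 50 CPM or more, with the largest ratio to the next mouse after adding 5 CPM. Values per mouse were compared between genotypes with an exact two-sided permutation test, which cannot give less than 0.1 for 3 against 3 mice or 0.133 for 4 against 2. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3.

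Alternatives covered other hashtag calls (MULTIseqDemux, and quantile 0.999), no cell filter, no filter on low counts, DESeq2's own test and its size factors, an absolute log2 fold change above 1, fits of the compared groups alone, equal total UMIs per mouse, G1 cells only, other-lineage cells left out, immunoglobulin genes left out and each mouse left out in turn. For clones they covered the clonotype identifiers deposited with the contigs and cells with exactly 1 heavy chain contig, and for light chains at least 5 UMIs. Phases were also scored without thinning and at 1000 UMIs, clusters formed at resolutions 0.25 and 1 and without cell cycle genes, and single-mouse genes ranked after adding 1 or 20 CPM. Added after the data were seen were the feature table's names, all 6 leukemic mice as 1 group, cells of the largest clone only, clusters of mature, plasma, other-lineage and low-quality cells left out, and the 5% of cells with the most UMIs left out of each mouse.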

Results

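B cells of mouse bone marrow were profiled cell by cell for gene expression, B cell receptor sequence and hashtag, to follow PAX5-ELN leukemia with and without Lgals1, which encodes galectin-1, a lectin that binds galactosides on cell surfaces and is made in the pre-B cell niche. The 7 mice were 1 pre-leukemic PAX5-ELN mouse, 3 leukemic Lgals1+/+ and 3 leukemic Lgals1-/- PAX5-ELN mice, as the hashtag table names them. The pre-leukemic mouse gave 1519 cells and 8187042 UMIs. Lgals1+/+ mice 1 to 3 gave 541, 997 and 1206 cells with 6431773, 11004541 and 9848670 UMIs. Lgals1-/- mice 1 to 3 gave 1314, 1456 and 1226 cells with 13574373, 16652177 and 19022155 UMIs. The median cell held 3542 UMIs in the pre-leukemic mouse and between 6454.5 (Lgals1+/+ mouse 3) and 14408 (Lgals1-/- mouse 3) in the leukemic mice. PAX5-ELN transcript was counted in every mouse, at 85.0 CPM in the pre-leukemic mouse, 50.8, 78.8 and 93.2 CPM in the Lgals1+/+ mice and 64.3, 94.7 and 60.9 CPM in the Lgals1-/- mice.

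Lgals1 (ENSMUSG00000068220, chromosome 15, 78926725 to 78930465, mm10) stood at 1314, 1802 and 976 CPM in the mice that the hashtag table names Lgals1+/+, and at 9.06, 10.3 and 6.73 CPM in those it names Lgals1-/-. The pre-leukemic mouse had 301 CPM. Between the leukemic genotypes Lgals1 fell by 7.26 on the log2 scale (SE 0.34, edgeR adjusted p = 0.00201, lower in 3 of 3 mice). The remaining 123, 172 and 128 UMIs per Lgals1-/- mouse were not separated into free RNA of the pool and reads of a transcribed remainder of the allele. Where the deletion lies is not given in the sources used here, so 5 prime reads outside it could leave Lgals1 signal in a Lgals1-/- mouse. Such reads would not account for the 9.06 and 10.3 CPM of hashtags 1 and 2, which the feature table names Lgals1+/+. Hashtag 3, which both sources name Lgals1-/-, had 6.73 CPM, against 1314, 1802 and 976 CPM of hashtags 4, 5 and 6. The levels argue against the feature table's names for hashtags 1 and 2. They also argue against its names for hashtags 4, 5 and 6, provided that the Lgals1-/- mice share the same deleted allele. The levels had, however, also guided the choice of names. With the names of the feature table, the difference was 6.76 with SE 1.97 in the other direction (edgeR adjusted p = 0.548). It also missed the threshold without Lgals1-/- mouse 1 (-7.27, edgeR adjusted p = 0.0566) and with MULTIseqDemux hashtag calls (-5.26, edgeR adjusted p = 0.127).

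**Figure D1:**
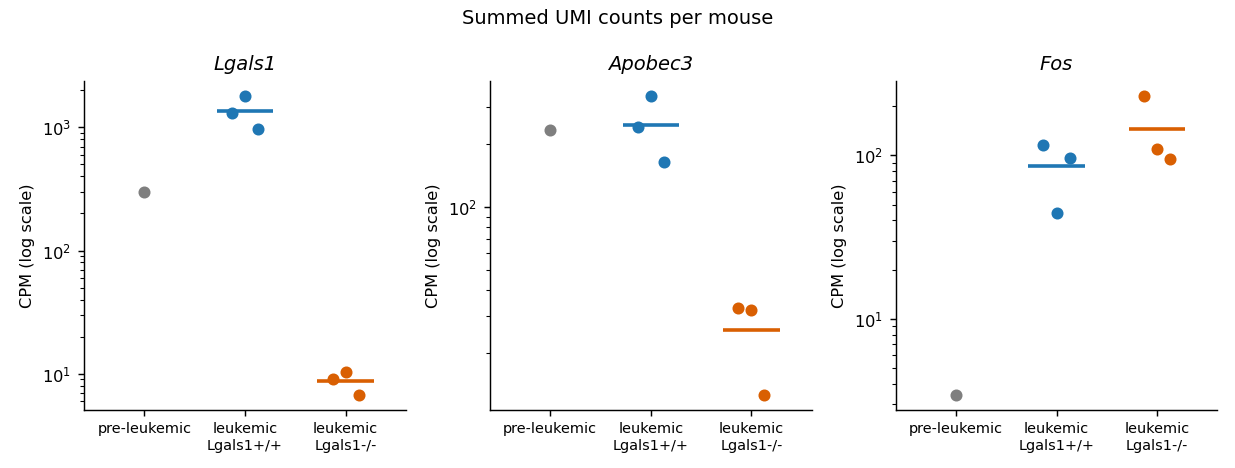
Level of named genes per mouse in CPM on a log axis, one point per mouse in the pre-leukemic (n = 1), leukemic Lgals1+/+ (n = 3) and leukemic Lgals1-/- (n = 3) groups as the hashtag table names them. Lgals1 lies between 976 and 1802 CPM in the Lgals1+/+ mice and between 6.73 and 10.3 CPM in the Lgals1-/- mice.

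Apart from Lgals1, a single gene passed the test between Lgals1-/- and Lgals1+/+ leukemias. Gm43305 (ENSMUSG00000105703, chromosome 14, 54292441 to 54297488), a predicted gene without a known function, stood at 2.64, 2.45 and 5.08 CPM in the Lgals1+/+ mice and rose to 122, 154 and 79.7 CPM in the Lgals1-/- mice (log2 fold change 5.15, SE 0.36, edgeR adjusted p = 0.0147). The pre-leukemic mouse, which expressed Lgals1, had 80.4 CPM, so the low level belonged to the Lgals1+/+ mice. Gm43305 was named after its values were seen. Its call ended, with 0 genes passing as higher, without Lgals1+/+ mouse 1 or 2, without Lgals1-/- mouse 1 or 2, in G1 cells and with the feature table's names. Apobec3, a cytidine deaminase that restricts retroviruses (ENSMUSG00000009585, chromosome 15, 79892058 to 79918218), stood at 240, 339 and 164 CPM in Lgals1+/+ and at 32.8, 32.1 and 12.7 CPM in Lgals1-/- mice without passing edgeR (log2 fold change -3.25, SE 0.42, edgeR adjusted p = 0.434), while DESeq2 called it (adjusted p = 5.01e-13). Akr1e1, an aldo-keto reductase, had 5.17 ± 2.29 and 0.0621 ± 0.0107 CPM (SD, n = 3 each, edgeR adjusted p = 0.0560, DESeq2 adjusted p = 7.78e-07).

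In all, 1 gene was higher and 1 lower among 13524 tested, and 733 had an unadjusted p under 0.05 (357 higher and 376 lower). DESeq2 called 44 genes, 25 higher and 19 lower, of which 2 were immunoglobulin V segments. Among 211 immunoglobulin segments tested, 35 had an unadjusted p under 0.05 and none passed with edgeR. The values of the 3 and 3 mice did not overlap for 1455 genes (10.8%, where chance gives 10%). The biological coefficient of variation was 0.432. No gene passed without Lgals1-/- mouse 1 or with the feature table's names. A single gene passed without Lgals1+/+ mouse 1 or without Lgals1-/- mouse 2.

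The other genes with the smallest unadjusted p, none of which passed with edgeR (adjusted p between 0.793 and 0.868), were the following. With Apobec3 and Akr1e1 they made 16 genes, all among the 44 called by DESeq2 (adjusted p between 5.01e-13 and 0.0446). Higher in Lgals1-/- mice, Gpm6b, a membrane proteolipid, had 20.5 ± 6.73 CPM in Lgals1+/+ and 98.7 ± 51.0 CPM in Lgals1-/- mice (SD, n = 3 each, here and for the following genes). Mmp14, a membrane-bound matrix protease, had 28.9 ± 2.12 and 56.0 ± 14.8 CPM. Dynlt1b, a dynein light chain, had 128 ± 11.3 and 236 ± 34.0 CPM, and Myl4, a myosin light chain, 121 ± 13.5 and 213 ± 25.5 CPM. Dnm1, the endocytic GTPase dynamin, had 1.87 ± 0.635 and 8.42 ± 2.42 CPM. Unc119 (log2 fold change 0.93), Zfp385a (1.28) and Mta3, a subunit of a chromatin remodelling complex (0.92), completed this direction. Lower in Lgals1-/- mice were Aldh1b1, a mitochondrial aldehyde dehydrogenase, at 47.7 ± 8.08 and 19.1 ± 3.26 CPM, Smco4 (35.6 ± 5.47 and 17.2 ± 3.47), Platr25 (19.7 ± 1.15 and 10.3 ± 1.83), and the scarce transcripts of Steap4, a metalloreductase (6.44 ± 3.72 and 0.534 ± 0.0584), Pid1 (2.61 ± 0.547 and 0.111 ± 0.0952) and Sdk1 (2.12 ± 1.23 and 0.0246 ± 0.0425).

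Genes of the pre-B cell state and of niche contact did not pass between the leukemic genotypes. Igll1 and Vpreb1, which encode the surrogate light chain that galectin-1 binds, had 1705 ± 125 and 1577 ± 210 CPM in Lgals1+/+ mice and 1687 ± 350 and 1343 ± 606 CPM in Lgals1-/- mice (SD, n = 3). Il7r, the receptor of the niche cytokine interleukin-7, had 499.5 ± 187 and 513 ± 351 CPM, and Cxcr4, the receptor of the niche chemokine Cxcl12, 56.9 ± 6.86 and 44.5 ± 8.17 CPM. Cd19 had 357 ± 42.7 and 302 ± 85.5 CPM and Rag1, of the V(D)J recombinase, 14.1 ± 4.19 and 9.46 ± 12.6 CPM. Their edgeR adjusted p lay between 0.896 and 0.998.

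By camera with the preset correlation, the G2/M and S phase lists were lower in the Lgals1-/- leukemias, calls that were lost when the correlation was estimated (adjusted p = 0.90 with an estimated correlation for each). All 53 G2/M genes had negative log2 fold changes (median -0.63, camera adjusted p = 8.48e-12) and so did 40 of 42 S phase genes (median -0.36, camera adjusted p = 2.38e-07). Nuf2, of the kinetochore, had 39.7 ± 12.04 CPM in Lgals1+/+ and 20.3 ± 2.73 CPM in Lgals1-/- mice, and Psrc1 27.3 ± 4.08 and 10.5 ± 5.42 CPM. Top2a, the topoisomerase of dividing cells, had 392 ± 140 CPM in Lgals1+/+ and 198 ± 21.5 CPM in Lgals1-/- mice. Rrm2, the inducible subunit of ribonucleotide reductase, had 305 ± 110 and 148 ± 23.1 CPM, Rad51, of recombination repair, 58.0 ± 15.5 and 35.55 ± 6.46 CPM, Tyms, which makes thymidylate, 180 ± 55.3 and 105 ± 7.08 CPM, and Mki67 339 ± 129 and 188 ± 34.6 CPM (SD, n = 3). Interferon-induced genes were also lower by camera (25 of 28 negative, median -0.61, camera adjusted p = 0.0316, adjusted p = 0.90 with an estimated correlation), among them the scarce Ifi44 (1.05 ± 1.40 and 0.120 ± 0.208 CPM), Trim30a with a log2 fold change of -0.78 and Ifi47 with -0.67. With edgeR no single member of the 3 lists passed over all genes or adjusted over the list alone, and DESeq2 called none. Unadjusted p under 0.05 was reached by 8 G2/M, 6 S phase and 0 interferon genes. In sums over G1 cells, both cell cycle lists were higher in Lgals1-/- mice (G2/M median 0.44, camera adjusted p = 0.00311, and S phase median 0.55, camera adjusted p = 8.47e-07). With the feature table's names all 3 lists turned, the S phase (camera adjusted p = 1.10e-13) and G2/M (1.46e-19) lists passing as higher and the interferon list not passing (0.289). The interferon call was lost without Lgals1+/+ mouse 3 (camera adjusted p = 0.987), Lgals1-/- mouse 1 (0.891) or Lgals1-/- mouse 3 (0.191). Relative to the median mouse of each gene, the G2/M genes had a median log2 level of 0.67, 0.66 and -0.43 in Lgals1+/+ mice 1 to 3, -0.45, -0.65 and 0 in Lgals1-/- mice 1 to 3 and 0.23 in the pre-leukemic mouse, so the genotypes overlapped, and 4 of the 53 genes were lower in all 3 Lgals1-/- mice than in every Lgals1+/+ mouse. The number of lists passing was 12 without Lgals1+/+ mouse 1, 11 without mouse 2, 7, 10 and 6 without Lgals1-/- mice 1, 2 and 3, and 6 without the pre-leukemic mouse.

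The other 29 lists did not pass between the genotypes. MHC class II genes, for antigen presentation, had a median of -0.90 (6 of 10 negative, camera adjusted p = 0.102), but passed as higher in cells of the largest clones alone (7.48e-05) and with mature, plasma, other-lineage and low-quality clusters left out (3.08e-05). In G1 cells they passed with a median of -1.69 (camera adjusted p = 1.84e-05), so the direction of this list depended on which cells were summed. The median was -0.36 for targets activated by PAX5 (15 of 19 negative, camera adjusted p = 0.0634), 0.33 for targets repressed by PAX5 (0.945), -0.22 for pro-B and pre-B identity genes (0.0737), 0.24 for glycolysis genes (0.0882) and 0.10 for MYC targets (0.25). It was -0.21 for components of the pre-B cell receptor, -0.06 for the interleukin-7 and STAT5 list, -0.24 for adhesion and homing and 0.03 for oxidative phosphorylation. Of markers of other cells, the neutrophil list had a median of -0.68 (0.697), monocytes and macrophages -0.39 (0.25), T cells 0.34 (0.974) and erythroid cells -0.11 (0.938). Adjusted p of the lists not given ran within the same range, up to 0.974. In the galectin list 1 of 7 genes was lower over all genes with edgeR. Adjusted over the list alone 1 was higher, Lgals2, and 1 lower, Lgals1, and DESeq2 called both over all genes (Lgals2 adjusted p = 0.00958). Lgals2 stood at 20.8, 6.91 and 0.0526 CPM in Lgals1-/- mice 1 to 3 and at 0, 0.0909 and 0 CPM in Lgals1+/+ mice 1 to 3, so the genotypes overlapped. The median of the galectin list was 0.13 while camera ranked it lower (0.313), and it was the only list that fry called (adjusted p = 0.0122). The list holds Lgals1 itself, the targeted gene whose level had guided the choice of names, so the fry call is no evidence on the other galectins. The T cell and plasma cell lists and the unfolded protein response list had positive medians with camera ranking them lower, and the list of stem and progenitor cells had a positive mean with a negative median.

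**Figure D2:**
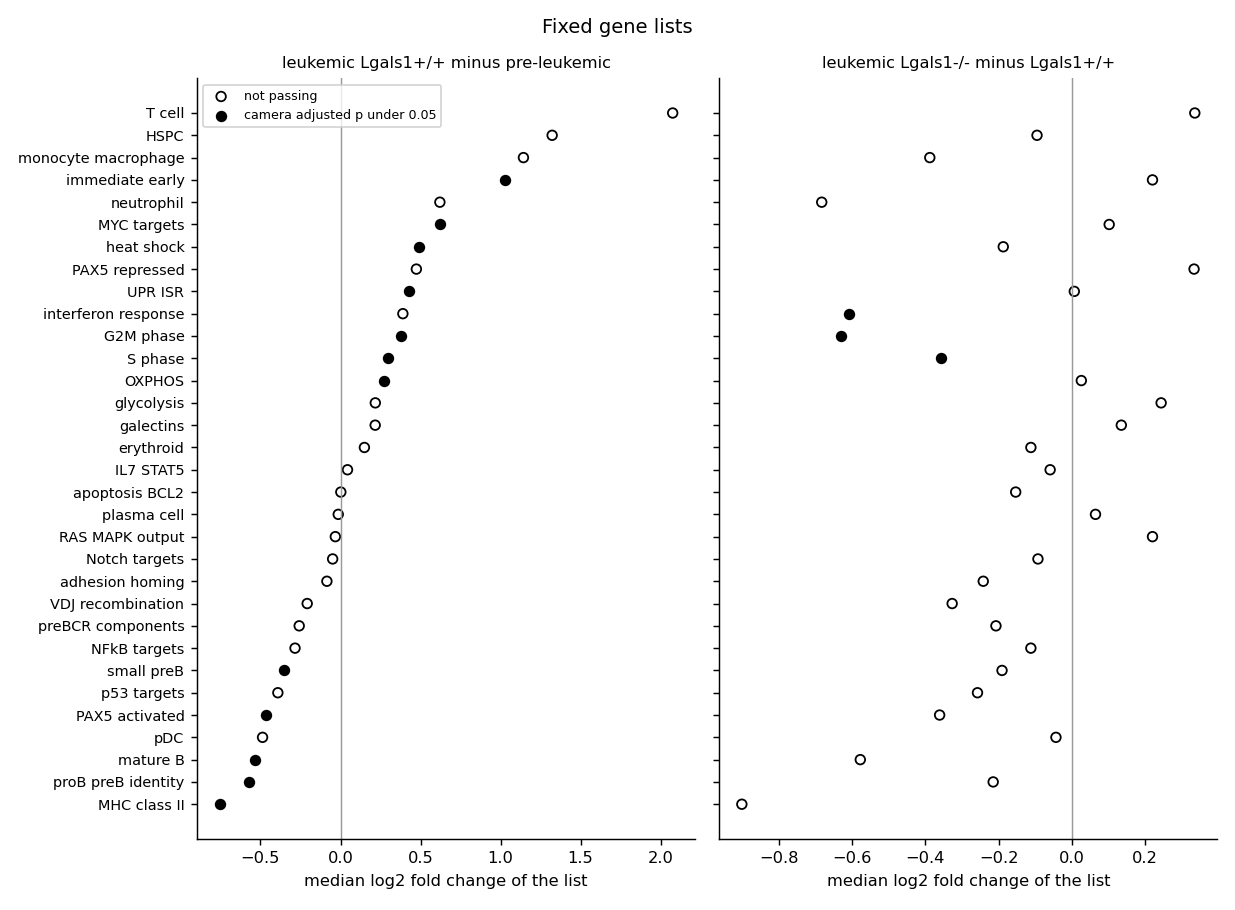
Median log2 fold change of each fixed gene list for Lgals1-/- against Lgals1+/+ leukemias and for Lgals1+/+ leukemias against the pre-leukemic mouse. Filled points pass camera with the preset correlation and open points do not. The G2/M list lies at -0.63 in the first comparison and at 0.38 in the second.

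Between leukemic Lgals1+/+ cells and pre-leukemic cells, 12 gene lists passed camera and no single gene passed edgeR. All 12 calls rest on 1 pre-leukemic mouse and were lost with an estimated correlation (adjusted p = 0.700 to 0.784) and with fry (lowest adjusted p = 0.568). At the preset correlation MYC targets were higher (23 of 25 positive, median 0.62, camera adjusted p = 1.05e-09, adjusted p = 0.700 with an estimated correlation), among them Tfrc, the transferrin receptor, with 40.2 CPM before leukemia and 64.4 ± 7.27 CPM in leukemia, and Gnl3, a nucleolar GTPase, with 56.7 and 93.1 ± 9.29 CPM (SD, n = 3). Oxidative phosphorylation genes (34 of 36 positive, median 0.27, camera adjusted p = 7.20e-05, adjusted p = 0.700 with an estimated correlation) held Cycs, which encodes cytochrome c, at 269.8 and 329.7 ± 13.7 CPM, and Cox5a, of cytochrome c oxidase, at 533 and 716 ± 86.9 CPM. The unfolded protein and integrated stress response (17 of 18 positive, median 0.43, camera adjusted p = 0.000427, adjusted p = 0.700 with an estimated correlation) held Asns, asparagine synthetase, at 5.86 and 22.0 ± 11.5 CPM, and Atf4, a transcription factor of that response, at 75.1 and 115 ± 24.2 CPM. Immediate early genes (17 of 21 positive, median 1.03, camera adjusted p = 0.00248, adjusted p = 0.700 with an estimated correlation) held Fos, an AP-1 subunit, at 3.42 and 85.6 ± 36.9 CPM, and Fosb at 1.47 and 17.4 ± 12.2 CPM. Heat shock genes (10 of 12 positive, median 0.49, camera adjusted p = 0.00599, adjusted p = 0.700 with an estimated correlation) held the scarce Bag3, a cochaperone, at 0.366 and 8.30 ± 10.5 CPM, Hspb1 at 0 counts and 1.09 ± 1.23 CPM, and Hspa1a at 13.9 and 45.3 ± 17.1 CPM. S phase genes (41 of 42 positive, median 0.30, camera adjusted p = 0.000282) and G2/M genes (50 of 53 positive, median 0.38, camera adjusted p = 0.0115) were higher too (adjusted p = 0.760 and 0.784 with an estimated correlation). They held Cdc45 at 26.9 and 32.2 ± 7.24 CPM and Nasp at 119 and 165 ± 51.8 CPM, and Cbx5 at 73.2 and 100.02 ± 42.8 CPM and Rangap1 at 54.6 and 71.3 ± 26.0 CPM. Both lists turned with the feature table's names, passing as lower (camera adjusted p = 0.0397 and 7.00e-06), and were ranked lower without passing in G1 cells (0.341 and 0.133).

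Lower in the leukemias at the preset correlation were 5 lists of B cell development and identity (adjusted p = 0.700 with an estimated correlation for each). Pro-B and pre-B identity genes (15 of 17 negative, median -0.57, camera adjusted p = 6.60e-06, adjusted p = 0.700 with an estimated correlation) held Dntt, the terminal transferase that adds nucleotides at V(D)J junctions, at 452 CPM before leukemia and 17.4 ± 21.0 CPM in leukemia, Myb at 421 and 166 ± 26.1 CPM, and Lef1 at 348 and 151 ± 33.3 CPM (SD, n = 3). Targets activated by PAX5 (17 of 19 negative, median -0.46, camera adjusted p = 0.00101, adjusted p = 0.700 with an estimated correlation) held Lef1 as well and Blnk, the adaptor of pre-B cell receptor signalling, at 39.5 and 7.34 ± 6.28 CPM. Mature B cell genes (13 of 17 negative, median -0.53, camera adjusted p = 0.00692, adjusted p = 0.700 with an estimated correlation) held Ighd at 19.5 and 5.18 CPM but also Klf2, a regulator of lymphocyte trafficking, at 162 and 546 ± 404 CPM. MHC class II genes (9 of 10 negative, median -0.75, camera adjusted p = 0.0287, adjusted p = 0.700 with an estimated correlation) held H2-Oa at 28.6 and 14.5 ± 6.67 CPM and H2-Ob at 70.1 and 34.8 CPM. Small pre-B genes (12 of 15 negative, median -0.35, camera adjusted p = 0.0385, adjusted p = 0.700 with an estimated correlation) held Btg1 at 393 and 174 ± 58.8 CPM, Rag2 at 75.2 and 14.9 CPM and, in the other direction, Cd2 at 34.1 and 90.5 ± 56.7 CPM. The calls for pro-B and pre-B identity, MYC targets and the stress response passed under all 12 other settings with the preset correlation. The G2/M call ended without Lgals1+/+ mouse 1 (camera adjusted p = 0.476) or mouse 2 (0.580), the S phase call without mouse 1 (0.129), the immediate early call without mouse 3 (0.0874), the mature B call without mouse 1 (0.0563) or mouse 2 (0.277), and the small pre-B and MHC class II calls without mouse 2 (0.209 and 0.346). With the clusters of mature, plasma, other-lineage and low-quality cells left out, the mature B (0.593), MHC class II (0.157) and small pre-B (0.0748) calls ended. In G1 cells the calls for targets activated by PAX5 (0.0704), mature B (0.230), MHC class II (0.326) and small pre-B genes (0.632) ended, and with the feature table's names those for oxidative phosphorylation (0.211), heat shock (0.188) and small pre-B genes (0.0566). Over all genes no list member passed with edgeR, while DESeq2 called Fos (adjusted p = 5.61e-09), Lgals1 (4.49e-06), Gbp3 (0.00373) and Fosb (0.0106). With edgeR adjusted over the list alone, 1 gene was higher in each of the immediate early (Fos), galectin (Lgals1) and interferon (Gbp3) lists and 0 in the other lists.

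With edgeR 0 genes passed against the pre-leukemic mouse (smallest adjusted p = 0.167), 492 had an unadjusted p under 0.05 (212 higher and 280 lower) and DESeq2 called 32 (16 higher and 16 lower, 5 of them V segments). The single mouse on the pre-leukemic side limits this comparison. Without Lgals1+/+ mouse 3, 1 gene passed. The smallest adjusted p belonged to Gm43305 (80.4 against 3.39 ± 1.46 CPM, log2 fold change -4.37, SE 0.40). The leukemic values lay all on 1 side of the pre-leukemic value for 7940 genes (58.7%, where chance gives 50%). Of the 16 genes with the smallest unadjusted p, Fos included, DESeq2 called all but Acsbg1 and Galns (14 genes, adjusted p between 5.61e-09 and 0.0374). Among them, Lgals1 stood at 301 CPM before leukemia and 1364 ± 415 CPM in leukemia (log2 fold change 2.38, SE 0.42), S100a4, a calcium-binding protein of motile cells, at 33.6 and 669 ± 470 CPM, Gbp3, an interferon-induced GTPase, at 17.6 and 53.9 ± 2.52 CPM, Cbr3, a carbonyl reductase, at 4.64 and 16.6 ± 4.6 CPM, and Galns, a lysosomal sulfatase, at 9.53 and 17.8 ± 0.768 CPM. Crxos stood at 1.59 and 10.1 ± 2.87 CPM. Acsbg1, an acyl-CoA synthetase, had 0 counts before leukemia and 4.07 ± 1.1 CPM in leukemia, at least 11.1-fold higher than the floor of 3 counts in the pre-leukemic mouse. In the other direction Dhrs3, a retinaldehyde reductase, had 56.4 CPM and 5.59 ± 1.61 CPM (edgeR adjusted p = 0.713), Bfsp2 173 and 27.4 ± 3.83 CPM, Slc30a5, a zinc transporter, 191 and 55.7 ± 6.44 CPM, Srfbp1 156 and 35.2 ± 10.7 CPM, Tspan13 438 and 183 ± 26.2 CPM, Kansl1l 170 and 68.6 ± 4.43 CPM, Mylk, the myosin light chain kinase, 12.9 and 0.278 ± 0.125 CPM, and Igf1, a growth factor, 20.8 and 0.223 ± 0.234 CPM. Igll1 (2759 CPM before leukemia), Vpreb1 (2573), Il7r (969), Rag1 (63.4), Cd19 (387), Mki67 (286) and Cxcr4 (58.8) did not pass either.

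Lists that did not pass against the pre-leukemic mouse included V(D)J recombination (median -0.21, camera adjusted p = 0.0605), p53 targets (-0.39, 0.0609), components of the pre-B cell receptor (-0.26, 0.0891), targets repressed by PAX5 (0.47, 0.259), adhesion and homing (-0.09, 0.224), interferon response (0.39, 0.408) and interleukin-7 and STAT5 (0.04, 0.766). Markers of other cells had positive medians for T cells (2.08, 0.256), monocytes and macrophages (1.14, 0.256) and neutrophils (0.62, 0.410, ranked lower by camera), from transcripts such as Cd3d at 0.122 CPM before leukemia. Median, mean or test also differed in sign for the NF-kB, Notch, RAS, apoptosis and erythroid lists. Across the lists the highest adjusted p was 0.980 (Notch targets). Lists of natural killer cells (3 of 9 genes measured), basophils and mast cells (0 of 7), platelets (1 of 6) and stroma or endothelium (3 of 12) were too small to test. With all 6 leukemic mice against the pre-leukemic mouse, a comparison without genotype names, edgeR called 0 genes (725 unadjusted) and camera 17 lists, among them glycolysis (median 0.42, camera adjusted p = 0.0336) and components of the pre-B cell receptor (-0.32, 0.0336), and 0 with an estimated correlation. The S phase and G2/M lists did not pass there (adjusted p = 0.121 and 0.930).

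Each leukemia was dominated by a single B cell clone and the pre-leukemic mouse was not. The largest clone held 71 of 1306 cells in the pre-leukemic mouse (5.44%, 95% interval 4.27 to 6.81). It held 96.4% (94.3 to 97.9), 97.9% (96.7 to 98.8) and 90.7% (88.8 to 92.4) in Lgals1+/+ mice 1 to 3 and 92.5% (90.7 to 94.0), 97.8% (96.8 to 98.5) and 99.4% (98.7 to 99.7) in Lgals1-/- mice 1 to 3. The clones used IGHV5-9-1 with IGHJ4, IGHV5-12 with IGHJ4, IGHV1-26 with IGHJ3, IGHV1-26 with IGHJ3, IGHV9-2 with IGHJ4 and IGHV1-81 with IGHJ4 in that order. The IGHV1-26 clones differed, with CDR3 of 12 and 9 amino acids. The effective number of clones was 158 in the pre-leukemic mouse and between 1.01 and 1.21 in the leukemias. The shares averaged 95% ± 3.80 in Lgals1+/+ and 96.5% ± 3.6 in Lgals1-/- mice (SD, n = 3 each, difference 1.52 percentage points, exact permutation p = 0.6, where 0.1 is the smallest possible). The effective number averaged 1.11 ± 0.0901 and 1.08 ± 0.0840 (exact permutation p = 0.6, n = 3 each). Both differences changed sign without Lgals1+/+ mouse 3 (-0.62 percentage points and 0.0173 clones). With the clonotype identifiers deposited with the contigs, the largest held 4.98% in the pre-leukemic mouse, 87.1%, 86.0% and 64.0% in Lgals1+/+ mice 1 to 3 and 76.1%, 83.0% and 86.1% in Lgals1-/- mice 1 to 3 (means 79.0% ± 13.04 and 81.7% ± 5.13, SD, n = 3 each, exact permutation p = 0.9). A heavy chain contig was found in 77.3% (Lgals1+/+ mouse 2) to 89.9% (Lgals1-/- mouse 2) of cells.

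**Figure D3:**
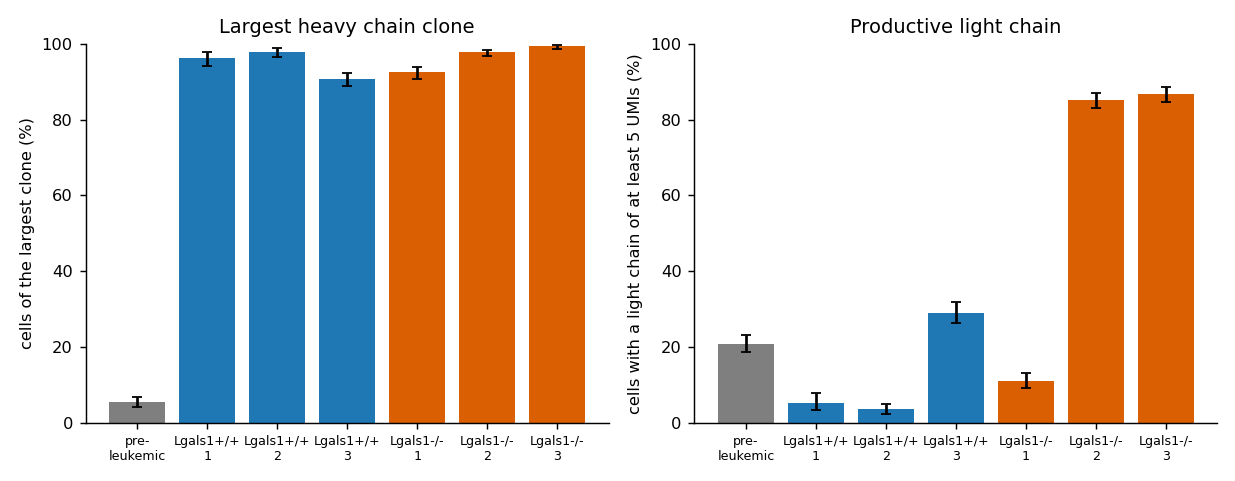
Share of cells in the largest heavy chain clone and share of cells with a productive light chain of at least 5 UMIs, in percent of cells with a heavy chain contig, for each of the 7 mice. Bars are single mice and error bars exact 95% intervals. The largest clone holds 5.44% in the pre-leukemic mouse and between 90.7% and 99.4% in the leukemic mice.

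Light chain rearrangement split the leukemias by mouse. Of cells with a heavy chain, 91.4% in Lgals1-/- mouse 2 and 87.2% in Lgals1-/- mouse 3 also had a productive light chain, against 23.9% in Lgals1-/- mouse 1, 12.7%, 13.9% and 34.4% in Lgals1+/+ mice 1 to 3 and 33.6% in the pre-leukemic mouse. With at least 5 UMIs per light chain the shares were 85.3%, 86.8%, 11%, 5.30%, 3.50%, 29.0% and 20.9% in the same order. Neutrophil-like cells, which make no light chain, had one in 13.8% of 80 cells and one of at least 5 UMIs in 11.3% (median depth 5183 UMIs), and T-like cells in 13.3% and 6.67% of 15 cells (6837 UMIs). These control shares were over all such cells, with or without a heavy chain contig. A heavy chain contig of at least 5 UMIs was found in 7.5% of the neutrophil-like and 46.7% of the T-like cells, so this background is rough. The shares of Lgals1+/+ mice 1 and 2 (median depths 9906 and 10351 UMIs) were at about its level, as was that of Lgals1-/- mouse 1 with at least 5 UMIs. The light chains of the clones were counted from contigs of at least 5 UMIs. In Lgals1-/- mouse 2 the clone carried IGKV4-57 with IGKJ4 in 1070 of 1280 cells, and in mouse 3 IGKV19-93 with IGKJ2 in 927 of 1074 cells. In Lgals1+/+ mouse 3 the clone carried IGKV3-10 with IGKJ5 in 139 of 929 cells (15%, median 29 UMIs among these contigs). The genotypes averaged 20.3% ± 12.2 (Lgals1+/+) and 67.5% ± 37.8 (Lgals1-/-) (SD, n = 3 each, difference 47.2 percentage points, exact permutation p = 0.2). With the feature table's names the difference was -20.6 percentage points (exact permutation p = 0.533).

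The share of cells scored in S or G2/M phase differed between mice of the same genotype. At 2000 UMIs per cell the shares were 67.3% and 65.6% in Lgals1+/+ mice 1 and 2, 67.2% in Lgals1-/- mouse 3, 36.6% and 26.4% in Lgals1-/- mice 1 and 2, 24.1% in Lgals1+/+ mouse 3 and 26.1% in the pre-leukemic mouse. Without thinning they were 63.2%, 64.1%, 69.0%, 33.5%, 24.9%, 22.3% and 23.4%. Cells too shallow for thinning numbered 37, 21, 13, 39, 62, 70 and 138 in that order. Top2a stood at 490, 455, 219, 199, 176, 233 and 337 CPM and Mki67 at 440, 383, 225, 183, 156, 194 and 286 CPM in the same order. The shares of Lgals1-/- mouse 3 (67.2%, Top2a 219 CPM) and of the pre-leukemic mouse (26.1%, Top2a 337 CPM) thus went against their Top2a levels. No order of the mice is read from the shares. Free RNA of the pool, which enters phase scores, was not separated. The genotypes averaged 52.3% ± 24.4 (Lgals1+/+) and 43.4% ± 21.2 (Lgals1-/-) (SD, n = 3 each, difference -8.91 percentage points, exact permutation p = 0.9). The difference ran from -23.0 without Lgals1+/+ mouse 3 to -0.41 without Lgals1-/- mouse 2 and was 24.5 with the feature table's names (exact permutation p = 0.4).

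Many leukemic cells lay in clusters filled mainly by a single mouse. Of 16 clusters, 8 drew over 80% of their cells from 1 mouse, and 68.7% of leukemic cells lay in a cluster of their own mouse, from 0% in Lgals1+/+ mouse 1 to 97.3% in Lgals1-/- mouse 3. With MULTIseqDemux hashtag calls the share was 48.1%, and that of Lgals1-/- mouse 2 was 27.5% in place of 81.0% and that of Lgals1+/+ mouse 2 was 0% in place of 43.8%. A pro-B-like cluster of 1199 cells, raised for Kit, Dntt, Igll1, Vpreb1, Il7r and Erg, held 75.8% of the pre-leukemic cells (73.6 to 78.0) and at most 2.57% of any leukemia. Cells that mixed across mice were immature or mature B-like (296 cells, from 0.163% of Lgals1-/- mouse 3 to 7.21% of Lgals1+/+ mouse 3) and neutrophil-like (80 cells, 0.185% to 1.83%). The small T-like cluster (15 cells) drew 10 cells from Lgals1-/- mouse 1, and the plasma-like one (11 cells) held 0 cells of Lgals1-/- mice 1 and 3. Clusters 0 and 1 were cycling-like and held 940 and 224 cells. Cluster 3, raised for Mki67, Top2a and Cdk1 but below the share of markers asked for, held 13.8% of Lgals1-/- mouse 1 and 8.45% of mouse 2, and cluster 5, with 3 of 7 small pre-B markers, 70.1% of Lgals1+/+ mouse 3. Since different clusters held the cycling cells of different mice, cluster sizes were compared by number only. The exact permutation test cannot pass with 3 against 3 mice (smallest p = 0.1, 0.32 adjusted over the 16 clusters). Cluster 0 held 30% ± 14.4 of cells in Lgals1+/+ and 0.787% ± 1.22 in Lgals1-/- mice (SD, n = 3 each), without overlap (exact permutation p = 0.1, and 0.267 with the feature table's names). Clusters 5, 8, 9 and 11, also lower in Lgals1-/- mice, reached the same p of 0.1 (exact permutation p = 0.4 to 0.533 with the feature table's names), while cluster 14, with 41.5% of Lgals1-/- mouse 3, held 536 cells.

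**Figure D4:**
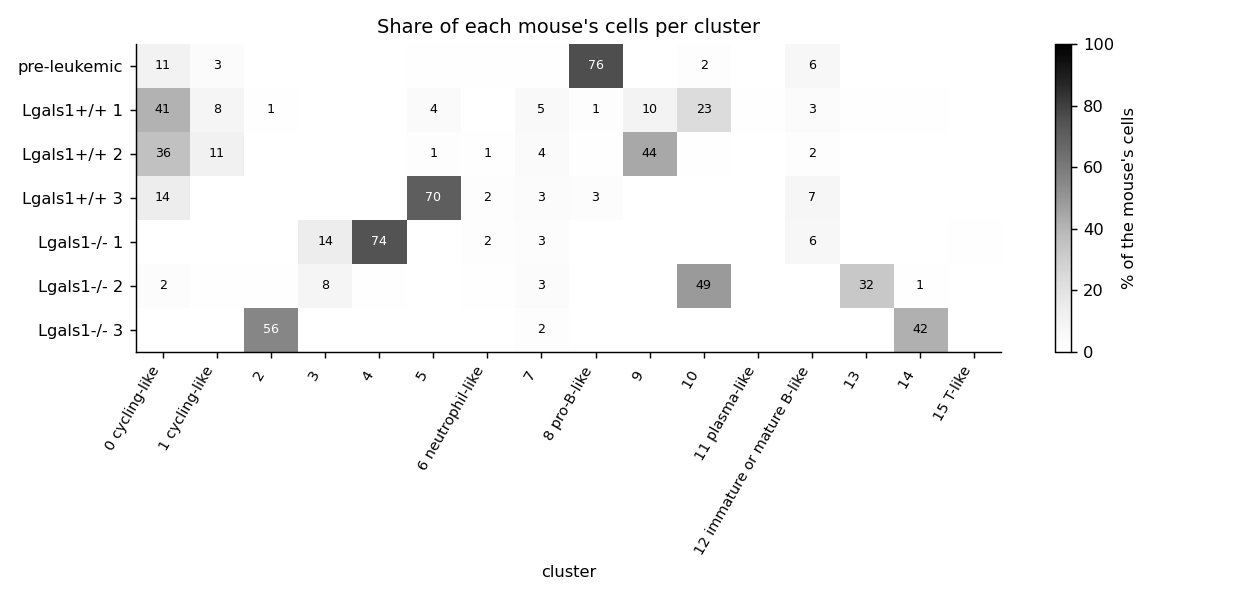
Share of each mouse's cells per cluster in percent, with mice as lines and clusters as columns, darker for larger shares and printed where at least 1%. The pro-B-like cluster holds 75.8% of the pre-leukemic cells, and several columns are filled mainly by a single mouse.

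The 5 genes with the largest ratio to the next mouse were taken for every mouse, whatever the ratio. Lgals1-/- mouse 3 expressed Lmo1, a LIM-only cofactor known as an oncogene of T cell leukemia, at 107 CPM (next mouse 6.92) and Dlk1, an imprinted Notch-like ligand, at 119 CPM (next 8.29). Lgals1-/- mouse 1 expressed Olig3, a neural transcription factor, at 87.7 CPM (next 1.54) and Ifitm1, an interferon-induced membrane gene, at 322 CPM (next 75.3). Lgals1-/- mouse 2 had Endou at 187 CPM (next 62.0) and Spp1, which encodes osteopontin, at 211 CPM (next 112). Lgals1+/+ mouse 3 had Ly6k at 192 CPM (next 10.5), Ly6a, the stem cell antigen Sca-1, at 1205 CPM (next 429) and Ifitm3 at 312 CPM (next 111). Lgals1+/+ mouse 2 had Xlr, an X-linked lymphocyte gene, at 106 CPM (next 1.1), and the neutrophil granule genes Camp at 473 CPM (next 154), Lcn2 at 309 CPM and Ltf at 104 CPM. Neutrophil-like cells made 1.1% of that mouse's cells, and 1.82% of Lgals1+/+ mouse 3 and 1.83% of Lgals1-/- mouse 1, where Camp stood at 95.4 and 137 CPM. Lgals1+/+ mouse 1 had Serpinh1, a collagen chaperone, at 275 CPM (next 90.9) and Jchain at 617 CPM (next 322). The pre-leukemic mouse stood out by Dntt at 452 CPM (next 41.2). These genes were picked for being highest in 1 mouse, so their order carries no test.

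**Figure D5:**
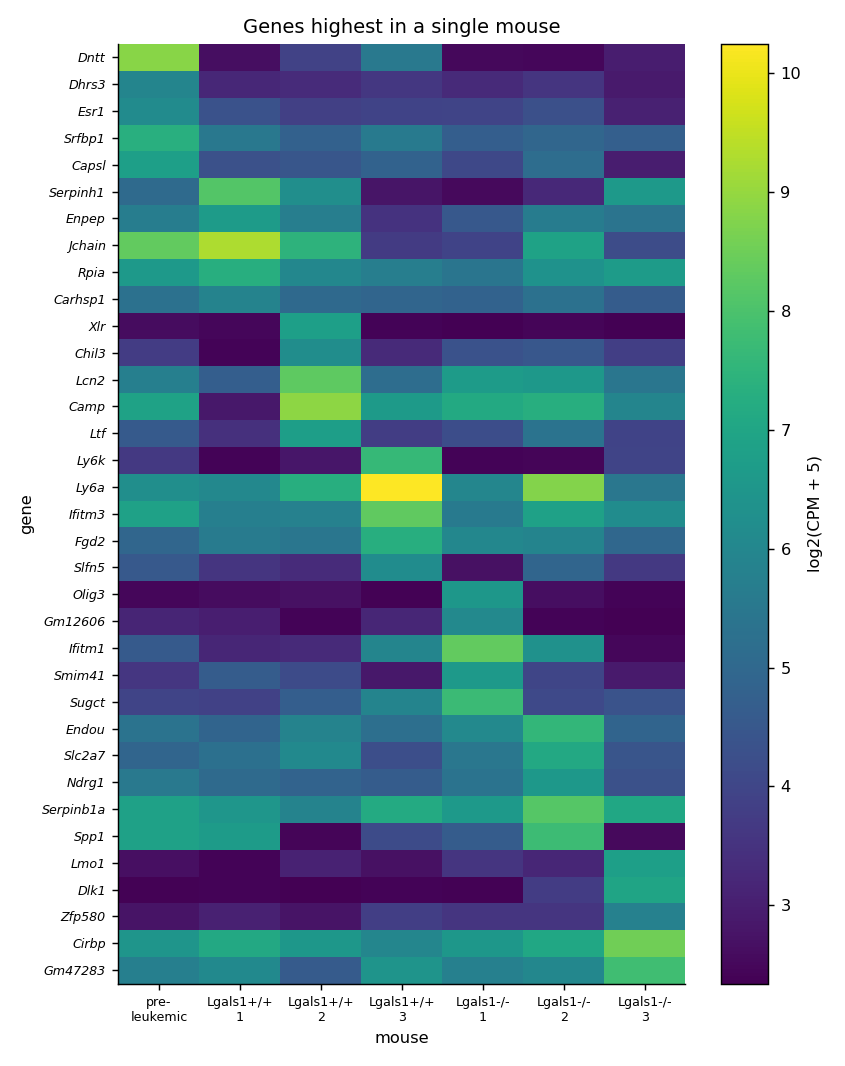
Level of the 35 genes highest in a single mouse, 5 per mouse, as log2 of CPM plus 5, with genes as lines and the 7 mice as columns. Dntt reaches 452 CPM in the pre-leukemic mouse, and Olig3 reaches 87.7 CPM in Lgals1-/- mouse 1.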

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

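The count of cells with a light chain alone was chosen after the contigs had been examined, and no explanation of it was tested. In Lgals1-/- mouse 3, 65 of 1226 cells (5.30%, 95% interval 4.12 to 6.71) had a light chain contig of at least 5 UMIs and no heavy chain contig, cells that the clone comparison leaves out. The pre-leukemic mouse, taken as the control, had 1.51% (0.962 to 2.26, 23 of 1519 cells). In Lgals1+/+ mouse 1 the count was 0 of 541 cells, and in the other leukemic mice it ran from 0.201% (Lgals1+/+ mouse 2) to 0.912% (Lgals1+/+ mouse 3). Of the 65 cells, 64 carried IGKV19-93, the light chain gene of that mouse's clone.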

How the results depend on the processing

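The feature table's names, all 6 leukemic mice as 1 group, the largest clone alone, left-out clusters and the left-out 5% of cells with most UMIs were settings chosen after seeing the data. Of 133 alternative values, 101 counted as the same, 25 moved, 2 lost their call and 5 reversed. For Lgals1, the same meant a kept direction and call, and for values per mouse a kept sign only. For counts of genes and lists it meant a number again 0 or within 1.5 times, and for cluster shares a shift under 1 SD between mice. The members behind a count can thus change. Without Lgals1+/+ mouse 2, for example, 2 genes passed between genotypes, but 0 were higher and 2 lower. The cause of the changes was not tested. Between genotypes the 2 genes became 44 with DESeq2, 1 with MULTIseqDemux, 1 in G1 cells and 0 with the feature table's names, and 0 to 3 when a mouse was left out. The 3 lists became 21 in G1 cells, 0 with an estimated correlation, 1 with fry, 9 with the feature table's names, 8 in the largest clone, 7 with mature, plasma, other-lineage and low-quality clusters left out, and 4 to 12 without a mouse. Against the pre-leukemic mouse the 0 genes became 32 with DESeq2, 1 with no filter on low counts, 1 with MULTIseqDemux and 0 to 1 without a mouse, and the 12 lists 0 with an estimated correlation, 0 with fry and 10 to 16 without a mouse. Lgals1 was -5.26 and no longer called with MULTIseqDemux, which called 1050 HTODemux doublets singlets, 6.76 with the feature table's names, and -7.47 to -6.99 without a mouse (-7.27, not called, without Lgals1-/- mouse 1). Without Lgals1+/+ mouse 3 the clone share difference reversed to -0.62 (range -0.62 to 3.55) and the effective clones to 0.0173 (range -0.0814 to 0.0173). With the feature table's names light chains reversed to -20.6 and phases to 24.5; without a mouse they ran from 35.2 to 69.0 and from -23.0 to -0.41. With the deposited clonotype identifiers the clone share difference was 2.72 (means 79.0% and 81.7%) and the effective clones 1.66 and 1.49. The share of leukemic cells in clusters of their own mouse, 68.7%, ran from 48.1% (MULTIseqDemux) to 69.5%, and 32 of the 35 single-mouse genes were named again under each alternative. The scrublet alternative was not run, since scrublet marked no cell. Depth limits genes near the floor of 3 counts, 0.158 to 0.466 CPM per mouse.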

Other observations

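Tests chosen only after the result was seen were those of cycling in a single mouse and of the genes around Lgals1 and the copy number of chromosome 15, and the genes named in this part were chosen after their values were seen. The pre-leukemic repertoire was broad, with 794 clones in 1306 cells. IGHV5-6 was used by 136 cells (10.4%), IGHV2-2 by 129 (9.88%) and IGHV1-72 by 107 (8.19%). By clone, the IGHV1 family made 42.8%, IGHV5 23.7% and IGHV2 17.0%, and IGHJ4 was used by 39.6% of cells. Cells with the dominant clone of another mouse's leukemia numbered 4 in the pre-leukemic mouse (0.306% of cells with a heavy chain). In Lgals1-/- mouse 2 a second clone held 18 cells (1.38%). In Lgals1-/- mouse 1, 21 cells had an IGHV11-2 contig, and all 21 had IGKV14-126, 8 of them with at least 5 UMIs of both chains. This pairing is known from B-1a cells that bind phosphatidylcholine. Cells of the main clone with a further heavy chain contig were not left out of this count. Of the 21 cells, 5 lay in the immature or mature B-like and plasma-like clusters. IGKV14-126 was found in 93 cells of that mouse and in 0 of Lgals1-/- mouse 3, with 23 to 50 cells in the other 5 mice. With IGKJ2 it was also the commonest light chain in clone cells of Lgals1+/+ mice 1 and 2 and Lgals1-/- mouse 1. It was found there in 20, 42 and 74 clone cells, with medians of 2, 3 and 4 UMIs. Counted from contigs of at least 5 UMIs, Lgals1+/+ mouse 2 and Lgals1-/- mouse 1 had 14 and 31 such cells (medians of 7 and 8 UMIs).

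Genes of the sex chromosomes differed within the leukemic groups. The Y-linked gene Eif2s3y stood at 106 CPM in Lgals1+/+ mouse 3 and 88.7 CPM in Lgals1-/- mouse 3 and at or below 0.733 CPM in the other 5 mice. Xist, expressed from the inactive X chromosome, stood at 349 CPM in the pre-leukemic mouse, 252 and 103 CPM in Lgals1+/+ mouse 1 and Lgals1-/- mouse 2, and at 24.0 and 5.97 CPM in Lgals1+/+ mouse 2 and Lgals1-/- mouse 1, which had low levels of Eif2s3y (0.273 and 0.147 CPM) and less Xist than those 3 mice. Klrb1c, a natural killer receptor gene, stood at 123 CPM in the pre-leukemic mouse and 1.63 CPM in Lgals1-/- mouse 3, while Nkg7, of cytotoxic granules, was at or below 3.45 CPM in every mouse.

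In 3 leukemias, genes of a whole chromosome were higher than in the other mice. The median gene of chromosome 14 was 1.5-fold the median of the other mice in Lgals1-/- mouse 3 (220 genes), and that of chromosome 15 was 1.33-fold in both Lgals1+/+ mouse 2 and Lgals1-/- mouse 1 (241 genes). The chromosome 15 ratio was 1.11 in Lgals1-/- mouse 2, whose chromosome 6 reached 1.12, and between 0.82 and 0.86 in the remaining mice. The chromosome exceeded the next autosome of the same mouse by at least 0.36 log2, and a small subset of cells is argued against by 89.3% or more of the cells of these mice lying above the median share of other cells. Both parts of each chromosome were raised, the lowest ratio being 1.28, so gain of the whole chromosome in the dominant clone may explain it, as a hypothesis. DNA was not measured, and Myc, on chromosome 15, did not follow, with 74.5 CPM in Lgals1+/+ mouse 2, 241 CPM in Lgals1-/- mouse 1 and 301 CPM in Lgals1+/+ mouse 3.

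The S phase and G2/M lists were lower in the Lgals1-/- leukemias by camera, a call lost with an estimated correlation (adjusted p = 0.90) and turned with the feature table's names (adjusted p = 1.10e-13 and 1.46e-19). A difference in depth between mice stays open: the G2/M median was -0.63 with each mouse thinned to equal total UMIs, but values are scaled to the totals, so thinning could hardly move it and the bound set for that test decided nothing, and UMIs per cell were not matched. In G1 cells the G2/M median was 0.44, but phases are called from these same genes, so that test could not decide whether the share of cycling cells explains the lists. Both lists passed camera as lower without each mouse in turn (highest adjusted p = 0.0294), so the call at the preset correlation did not hang on a single mouse. That correlation of 0.01 lies far below the estimated 0.86 (G2/M) and 0.73 (S phase), so these passes cannot decide on cycling of a single mouse. Lgals1+/+ mice 1 and 2 stood apart from the rest, and genotype and mouse stay open. Of the 10 splits of the 6 leukemic mice into 3 and 3, all 10 gave at least the 3 lists of the real split, with 18 as the highest other. The number of lists passing therefore did not set the genotype split apart. These counts were made at the preset correlation of 0.01. They cannot tell structure among the mice from correlation of genes within the lists. The real split gave 2 genes and the highest other 1, so 1 split reached 2, and 10 splits are too few for a share under 0.05. Of these 2 genes 1 was Lgals1, whose level had guided the choice of names, so that lead was partly fixed in advance. Apart from Lgals1 the real split gave 1 gene, as many as the highest other.

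Apobec3, whose level is known to differ between mouse strains, lies close to Lgals1 on chromosome 15 and stood lower in all 3 Lgals1-/- mice, a difference that DESeq2 called and edgeR did not. Other cells in the samples are argued against, since the log2 fold change was -3.27 in cells of the largest clones, and copy number of chromosome 15 too, since the lowest Lgals1+/+ level was 5.002-fold the highest Lgals1-/- level. A segment of another strain carried along with the targeted allele is a candidate explanation that stays open: of 59 further genes tested within 2 Mb of Lgals1, 6 had an unadjusted p under 0.05, a count that 10.8% of 11649 windows elsewhere reached or exceeded (median 3). Among the 6, Cbx7 and Cbx6 were lower in the Lgals1-/- mice without overlap. Cbx7 stood at 5.29, 9.54 and 5.79 CPM in Lgals1+/+ and 3.68, 1.74 and 1.95 CPM in Lgals1-/- mice, and Cbx6 at 6.37, 15.3 and 10.5 CPM and at 1.33, 0.0601 and 2.63 CPM. The other genes overlapped between genotypes, with Dmc1 lower and Gm10863, Maff and Lgals2 higher by log2 fold change. Lgals2, next to Lgals1, stood at 20.8, 6.91 and 0.0526 CPM in the Lgals1-/- mice and at or below 0.0909 CPM in the Lgals1+/+ mice. The deleted allele's own effect on its neighbours was not tested, and the genotype names rest on the hashtag table.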
